A study of Rattus norvegicus with 24 samples.

How the data were processed

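Left kidneys of male rats of 3 strains were compared: the inbred Dahl salt-sensitive strain (S) and the congenic substrains ET3x1 and ET3x2. Such substrains carry alleles of the salt-resistant strain on an S background, here around the endothelin 3 gene (Edn3) on chromosome 3, from general knowledge of these strains. The rats ate a 0.4% NaCl diet until 39 to 41 days of age and a 2% NaCl diet for 28 days, and the kidneys were taken at 67 to 69 days of age. Per the labels, equal amounts of total RNA were pooled, from 2 rats per pool in S and from 3 rats per pool in ET3x1 and ET3x2. This gave 4 pools per strain (S pools A, B, C and D, ET3x1 pools E, F, G and H, ET3x2 pools I, J, K and L), 12 pools and 32 rats in all. Each pool was hybridised once to each of the Affymetrix arrays RAE230A and RAE230B after oligo(dT)-primed cDNA synthesis and biotin labelling, so that there were 24 arrays and the probe sets read mostly the 3' part of transcripts. One pool was taken as one replicate.

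The deposited tables gave 1 value per probe set and pool. The deposited values were treated as log2 signal, which was inferred from their range: 4.97 to 15.2 on RAE230A and 4.10 to 13.5 on RAE230B, with no negative value. Summarisation, background correction, normalisation and scanner were not given in the sources used here. A log2 fold change is therefore a difference of deposited signals, and where 1 group's mean lay under the level of the filter described further on, its size depends on a background that is not known, so that no fold is given. The medians of the 12 columns lay between 8.50 and 8.61 on RAE230A and between 7.55 and 7.62 on RAE230B, and the values were used without further scaling. Arrays give no read depth, and the number of arrays limits the precision.

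Gene symbols were taken from a rat RefSeq annotation of the assembly GRCr8 by matching each probe set's gene identifiers. That annotation was used only for names, chromosomes and the order of genes, and no coordinates are given. On RAE230A 12783 of 15866 probe sets had 1 symbol, 312 had several and 2771 had none. On RAE230B 7564 of 15276 had 1 symbol, 100 had several and 7612 had none. Of the probe sets with 1 symbol, 12748 and 7524 matched by gene identifier, 2 and 0 by accession, and 33 and 40 kept the name of the array's own table. A probe set with no symbol or with several is given by its probe set name and was left out of counts of genes. Such probe sets are described below as without a symbol. Sequences of the probes were not analysed here.

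The 57 control probe sets of each array were left out, as were probe sets whose mean over the 12 pools lay under the 30th percentile of their array (7.52 on RAE230A and 6.85 on RAE230B). This left 11106 and 10693 probe sets, 21799 in all, for 11218 genes, of which 1550 were on both arrays. Linear models were fitted to each array's 12 pools with limma 3.58.1 (lmFit, then eBayes with a trended prior) in R 4.3.3, without covariates because the labels give no batch. The 3 contrasts were ET3x1 against S, ET3x2 against S and ET3x2 against ET3x1, and the 3 groups shared one estimate of the spread. P-values are two-sided, were adjusted by Benjamini and Hochberg within array and contrast, and passed at an adjusted p under 0.05, and the counts of both arrays were added. Errors of fold changes are standard errors (SE) from the fit with 4 pools in each group, and group values are means with standard deviation (SD). The p-values measure the spread between pools of different rats, which is biological spread averaged over the 2 or 3 rats of a pool together with the spread of the assay. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

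Gene lists of transport, blood pressure, injury, immune, metabolic and cell-type genes were tested with camera at a preset inter-gene correlation of 0.01, on 1 probe set per gene (the highest mean, from RAE230A where a gene was on both arrays). A list needed 5 measured genes, and p-values were adjusted over the lists of a contrast. Of 33 lists, 29 were tested in this way. Each is also given with an inter-gene correlation estimated from the data, and fry served as a second set test. Members were also counted when adjusted over the list alone. Genes called on each chromosome were compared with those tested by Fisher's exact test, two-sided, adjusted over chromosomes. The overlap of both contrasts with S was set against 100 simulated pairs of unchanged groups that share the S pools, and against fits that gave each contrast its own pair of S pools.

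The groups, contrasts, filter, tests, threshold, gene lists, alternatives and the rule for the genes named were fixed before the data were examined. By that rule each comparison names, among probe sets past the threshold with 1 symbol, the 10 highest and the 10 lowest by log2 fold change (1 probe set per gene), up to 4 called members of each list described, up to 15 called genes on chromosome 3, and, called or not, a fixed set of genes, of which this text gives Edn3, Agt, Ace, Nr3c2, Slc12a1, Slc12a3, Scnn1a, Havcr1 and Lcn2. Probe sets without a symbol and other genes outside the rule were chosen after their values were seen. Edn3 had no tested probe set and is not analysed here, and 1 gene of that set is not reported.

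Alternatives were another filter or none, quantile normalisation, median centring, other variance priors, a fit of only the groups compared, weights by rats or by estimated array quality, adjustment over both arrays, an added 1.5-fold minimum, and leaving out each pool in turn. A covariate of the actin 5' minus 3' control signal, and leaving out pools A, B and J together, were chosen after seeing the data. Other offsets before taking logarithms had been foreseen for linear tables only and were not run, and camera has no robust prior, so that alternative was not run for lists.

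The pipeline was tested on simulated data of 21799 probe sets with planted log2 changes. The simulated noise was drawn independently for each probe set and pool, without the structure that real pools share. The rates given next may therefore not hold for the real data. For ET3x1 against S it recovered 81.3% of planted changes of 0.5, 97.0% of 1 and 100% of 2, with 22 false calls among 393. For ET3x2 against S the shares were 81.3%, 98.5% and 100%, with 15 false calls among 388, and for ET3x2 against ET3x1 they were 78.4%, 94.7% and 100%, with 16 among 380. The match of both arrays of a pool was checked on 100 probe sets present on both. All 12 pools correlated best with their own profile on the other array, with r between 0.507 and 0.890 across probe sets, against at most 0.792 for profiles of different pools.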

Results

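Kidney RNA of salt-sensitive S rats and of the congenic substrains ET3x1 and ET3x2 was compared after 28 days on a 2% NaCl diet, to ask which transcripts differ when salt-resistant alleles replace part of chromosome 3. The data were log2 signals of 21799 probe sets in 12 pools, 4 per strain. After testing, 96 probe sets differed between ET3x1 and S, 75 between ET3x2 and S and 323 between ET3x2 and ET3x1, where unadjusted p under 0.05 was met by 2583, 2369 and 2855 and chance alone gives 1090. On the first principal component, which held 31.3% of the variance on RAE230A and 36.7% on RAE230B, S pools A and B and ET3x2 pool J stood apart on both arrays. Their scores on RAE230A were 17.0, 17.8 and 14.3, and the next highest was 0.28 in pool C. At the low end lay ET3x1 pool G, at −14.6 on RAE230A and −17.0 on RAE230B, and S pool D, at −11.5 on RAE230B. In pools A, B and J the actin 5' minus 3' control signal, a measure of how complete the RNA was, was highest, at −1.27, −1.27 and −1.14 against −1.66 to −2.10 in the other 9.

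In ET3x1 kidneys nearly all called probe sets were higher than in S, among them those of Eif5b, Luc7l3, Sltm, Eea1, Jchain and Ccl5. Eif5b, which joins ribosomal subunits at the start codon, rose by 1.28 (log2, SE 0.11, 2.44-fold, adjusted p = 9.9e-05, n = 4 pools each). Luc7l3, a splicing factor, rose by 1.12 (SE 0.099, 2.18-fold, adjusted p = 9.9e-05), and Sltm, an RNA-binding nuclear scaffold protein, by 1.65 (SE 0.24, 3.15-fold, adjusted p = 0.00611). Eea1, the tether of early endosomes, rose by 1.25 (SE 0.14, adjusted p = 0.000847). Jchain, which links the units of polymeric antibodies, rose by 1.72 (SE 0.18, 3.28-fold, adjusted p = 0.000516), from 8.50 to 8.84 in the S pools to 9.68 to 10.64 in the ET3x1 pools, and the chemokine gene Ccl5 by 0.91 (SE 0.13, 1.88-fold, adjusted p = 0.00942). A second Jchain probe set, 1384208_at, rose by 0.50 (SE 0.079, adjusted p = 0.0104). The largest differences in signal among called probe sets lay in a pair without a symbol, 1388272_at with 4.95 (SE 0.24, adjusted p = 4.19e-08) and 1387902_a_at with 2.97 (SE 0.19, 7.83-fold, adjusted p = 7.32e-07). Another without a symbol, 1370967_at, rose by 1.39 (SE 0.16, adjusted p = 0.000629). The S means of 1388272_at (7.48) and Eea1 (6.53) lay under 7.52 and 6.85, the levels of mean signal below which probe sets of RAE230A and RAE230B were left out, so that the size of both differences depends on the unknown background.

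Of the other named genes higher in ET3x1, several lost their call when 1 pool was left out. Ubxn4, of endoplasmic reticulum protein degradation, rose by 1.76 (SE 0.30, 3.39-fold, adjusted p = 0.0150), a call that ended without pool C (log2 1.63, adjusted p = 0.0634) or pool E (1.77, 0.0575), with a difference of about the same size. Mgll, which degrades the endocannabinoid 2-arachidonoylglycerol, rose by 1.38 (adjusted p = 0.0200) and missed the threshold without pool C (0.0672), E (0.0765), F (0.0682) or G (0.0818), where the difference was 1.29 to 1.39. Arhgap5 rose by 1.19 (adjusted p = 0.0130, but 0.0565 without pool E), Wdfy1 by 1.17 (adjusted p = 0.0325) and, without a symbol, 1379555_at by 1.36 (adjusted p = 0.0115, but 0.0510 without pool E). The cholesterol synthesis gene Sc5d rose by 0.54 (SE 0.065, adjusted p = 0.00137) and kept its call without any 1 pool, and Atp6v1b1, a proton pump subunit of intercalated cells, by 0.33 (SE 0.069, adjusted p = 0.0483). Only 2 probe sets were lower, Itgb1 (integrin beta 1) at −0.73 (SE 0.12, adjusted p = 0.0173) and Selenot at −0.39 (SE 0.072, adjusted p = 0.0393). Itgb1 passed in none of the fits without pool A (0.050), B (0.0712), E (0.0644), F (0.0582) or G (0.0732), and for Wdfy1, Atp6v1b1 and Selenot most pools left out ended the call, with adjusted p up to 0.144, 0.161 and 0.167.

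The 96 probe sets called in ET3x1 against S were 94 higher and 2 lower, for 65 genes, 23 of them on RAE230A and 73 on RAE230B. The median absolute log2 fold change was 0.69, and 27 had no single symbol. The count fell to 57 without pool C and to 41 without pool E. Of the 27 probe sets named in this comparison, 15 lost their call without pool E. In all, 11 were past the threshold in every alternative that tested them: Jchain, Sltm, Eif5b, Eea1, Luc7l3, Rtel1, Esf1, Ccl5, 1388272_at, 1387902_a_at and 1370967_at. The filter at the 50th percentile left out Eea1, Luc7l3 and Rtel1, so that this alternative did not test them. Of the 23 named genes called here, 20 had other tested probe sets. In 1 of the 20 all probe sets were called, and in 9 some probe set had the opposite sign.

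Extracellular matrix and fibrosis genes were lower on balance in ET3x1 than in S, with 17 of 22 negative and a median of −0.12. The list passed with the preset correlation (adjusted p = 0.010, adjusted p = 0.880 with an estimated correlation), and fry gave an adjusted p of 0.635. None of its genes passed over all genes, while adjusted over the list alone Col4a1, of basement membrane collagen, was lower at −0.36 (SE 0.10, adjusted p = 0.0426) and Lox, which crosslinks collagen, at −0.34 (SE 0.094, adjusted p = 0.0426), which ended on leaving out any of 7 and 8 of the 12 pools (adjusted p up to 0.166). The mean of the list was highest in S pools A (0.17) and B (0.19) and 0.088 in ET3x2 pool J, the 3 pools that stood apart in actin 5' minus 3' signal, and between −0.14 and −0.0047 in the other 9. Without pool A the adjusted p was 0.0972, without B 0.139, without F 0.146 and without G 0.0615 with a median of −0.077, and without D the median was −0.19. Without A, B and J together the median was 0.0063 (adjusted p = 0.893). No list passed with an estimated correlation in this comparison (smallest adjusted p = 0.880) and none by fry.

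In ET3x2 kidneys the called genes Slc5a3, Rbm5 and Ubn2 were lower than in S, while Jchain and Rtel1 were again higher. Slc5a3, which takes up the osmolyte myo-inositol together with sodium, fell by 0.99 (log2, SE 0.083, adjusted p = 0.000173, n = 4 pools each), from 10.47 to 10.77 in the S pools to 9.48 to 9.72 in the ET3x2 pools. The splicing regulator Rbm5 fell by 0.99 (SE 0.13, adjusted p = 0.00612) and the chromatin protein gene Ubn2 by 0.84 (SE 0.12, adjusted p = 0.0104). Jchain rose by 1.21 (SE 0.18, 2.32-fold, adjusted p = 0.0113) and the helicase gene Rtel1 by 0.75 (SE 0.067, 1.68-fold, adjusted p = 5.86e-05). For Jchain's second probe set, 1384208_at, the difference of 0.35 missed the threshold (adjusted p = 0.0880). Among probe sets without a symbol, 1388272_at was higher in signal by 4.18 (SE 0.24, adjusted p = 4.41e-07, against the same dim S mean) and 1387902_a_at by 2.39 (SE 0.19, 5.23-fold, adjusted p = 1.42e-05), while 1376742_at, also without a symbol, fell by 1.72 (SE 0.21, adjusted p = 0.00294) and 1384948_at by 1.22 (SE 0.25, adjusted p = 0.0489). Without pools A, B and J together the adjusted p of Rbm5 and of Ubn2 was 0.0501 and that of Jchain 0.118, although over all alternatives the differences stayed between −1.08 and −0.88 for Rbm5, −0.93 and −0.75 for Ubn2, and 1.12 and 1.28 for Jchain.

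Of the other named genes lower in ET3x2 than in S, the GATA-type repressor gene Trps1 was at −1.04 (SE 0.17, adjusted p = 0.0193), the nucleotidase gene Entpd5 at −0.98 (SE 0.16, adjusted p = 0.0193), Zbtb20 at −0.93 (adjusted p = 0.0296), Mphosph8 at −0.93 (adjusted p = 0.0120), Zbtb41 at −0.85 (adjusted p = 0.0133), Sp1 at −0.79 (adjusted p = 0.0246) and Rbms3 at −0.77 (adjusted p = 0.0200). The ET3x2 means of Zbtb20 (6.31) and Zbtb41 (6.84) lay under the filter level of 6.85, so that the size of their differences depends on the background. Higher were Ckap4 by 0.55 (SE 0.092, adjusted p = 0.0438), Fads3 by 0.53 (0.0438), Uqcc6 by 0.51 (0.0362), Npl by 0.44 (0.0455), Mpv17 by 0.42 (0.0486), Smim1 by 0.41 (0.0154), Rnf126 by 0.37 (0.0486) and Rhoh by 0.34 (0.0321). Leaving out 1 pool ended 18 of the 28 named calls for pool A (adjusted p up to 0.177), 16 for C (0.129), 17 for I (0.180), 17 for K (0.205) and 15 for L (0.153), and Mphosph8 lost its call only without C among single pools (0.0548). Past the threshold in every alternative that tested them were 5 of the 28, Rtel1, Slc5a3, 1388272_at, 1387902_a_at and 1376742_at. Rtel1 was left out by the filter at the 50th percentile.

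The 75 probe sets called in ET3x2 against S were 14 higher and 61 lower, for 39 genes, with 9 on RAE230A and 66 on RAE230B, and 36 had no single symbol. Their median absolute log2 fold change was 0.60. The count depended on single pools of all 3 strains. It was 19 without pool A, 21 without C, 167 without D, 44 without E, 19 without I, 140 without J, 19 without K and 36 without L. Of 24 named genes called, 16 had other tested probe sets. In 0 of the 16 were all called, and in 5 some probe set had the opposite sign.

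Clock genes and interferon-response genes were lower on balance, and cell cycle genes higher, in ET3x2 than in S. In the circadian list 11 of 15 genes were negative, with a median of −0.23 (adjusted p = 0.000521, adjusted p = 0.611 with an estimated correlation), and Nr1d2, a repressor of the clock, was at −0.68 (SE 0.18, adjusted p = 0.0265 adjusted over the list alone), a call that ended without A, C, I, J or K (adjusted p up to 0.102). The list's mean was highest in S pool A, at 0.39. The median was −0.12 without pool A and −0.042 without A, B and J, where the adjusted p was 0.121. In the cell cycle list 12 of 13 were positive, with a median of 0.11 (adjusted p = 0.00859, adjusted p = 0.269 with an estimated correlation). Adjusted over the list alone, the mitotic kinase gene Cdk1 was higher by 0.41 (SE 0.090), the replication helicase gene Mcm5 by 0.27 (SE 0.076) and Ccnb2 by 0.26 (SE 0.070), where Mcm5 ended without K (adjusted p = 0.0608) and all 3 without A, B and J together (0.0612, 0.112 and 0.112). The adjusted p of the cell cycle list was 0.0617 without pool C, 0.0592 without A, B and J, and 0.0681 with the filter at the 50th percentile, which also gave 0.0681 for the interferon list. In the interferon list 9 of 13 were negative, with a median of −0.11 (adjusted p = 0.00859, adjusted p = 0.789 with an estimated correlation), and its mean was 0.52 in S pool D against −0.10 to 0.043 in the other 11 pools. Without pool D its median was 0.034 (adjusted p = 0.821), and without pool C −0.18. Without A, B and J together, which leaves S pools C and D, its median was −0.26 (camera adjusted p = 2.12e-06).

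Extracellular matrix genes were also lower on balance in ET3x2, with 16 of 22 negative and a median of −0.073 (adjusted p = 0.0176, adjusted p = 0.789 with an estimated correlation). This rested on pools A and B, without which the adjusted p was 0.117 and 0.386, and it also passed the threshold no longer without G (0.0648), I (0.0579) or L (0.0564). The median was −0.13 without C, −0.12 without D, and 0.0084 without A, B and J together. T and B cell markers were all positive, 8 of 8, with a median of 0.13. They missed the camera threshold (adjusted p = 0.0668, adjusted p = 0.455 with an estimated correlation) but passed in fry (0.0294), which asks only whether a list's genes move one way. Adjusted over the list alone, Cd3g was higher by 0.29 (SE 0.091) and Cd3e by 0.23 (SE 0.077), which ended on leaving out any of 6 and 7 of the 12 pools (adjusted p up to 0.124 and 0.150). The cell cycle list also passed in fry (0.00645), and the circadian (0.340) and interferon (0.593) lists did not. With an estimated correlation no list passed (smallest adjusted p = 0.269).

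**Figure D1:**
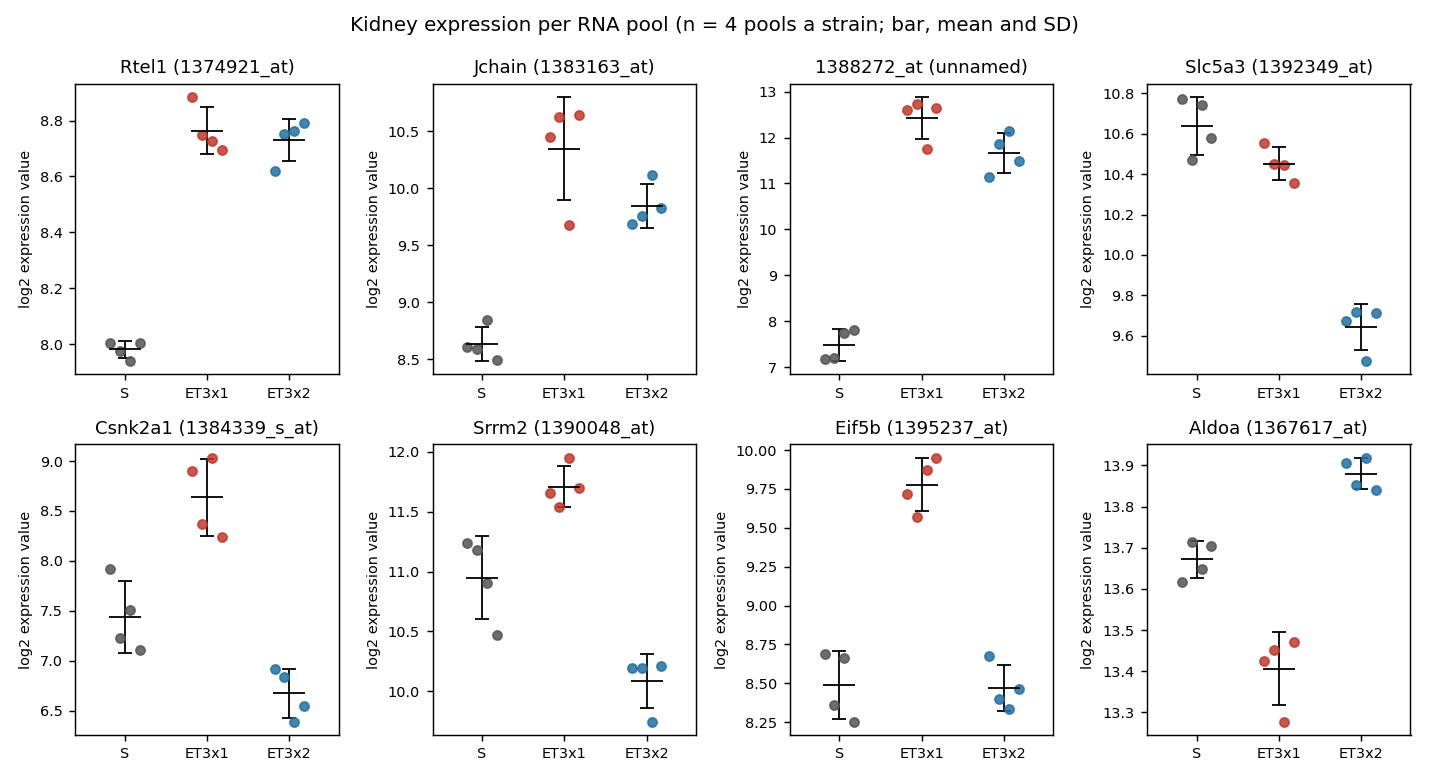
Log2 signal of 8 probe sets in the 12 pools, coloured by strain, where each point is 1 pool and bars show the mean and SD of the 4 pools of a strain. 1388272_at lay between 7.17 and 7.81 in S, 11.74 and 12.73 in ET3x1 and 11.13 and 12.15 in ET3x2, and Rtel1 between 7.94 and 8.01 in S and at 8.62 or more in both congenic strains.

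More probe sets differed between the congenic strains than between either and S, and 302 of the 323 were lower in ET3x2. Srrm2, a core protein of the spliceosome, fell by 1.62 (log2, SE 0.16, adjusted p = 0.000160, n = 4 pools each), from 11.54 to 11.95 in the ET3x1 pools to 9.75 to 10.21 in the ET3x2 pools. Csnk2a1, the catalytic subunit of casein kinase 2, fell by 1.96 (SE 0.20, adjusted p = 0.000177), Sltm by 1.68 (SE 0.24, adjusted p = 0.00213), Ubxn4 by 1.91 (SE 0.30, adjusted p = 0.00471) and Mgll by 1.80 (SE 0.22, adjusted p = 0.00124). Eprs1, which charges transfer RNA with glutamate and proline, was at −1.48 (SE 0.21, adjusted p = 0.00236), Entpd5 at −1.44 (SE 0.16, adjusted p = 0.000427) and Wdfy1 at −1.41 (SE 0.21, adjusted p = 0.00469). Lower with single pools deciding the call were the RNA helicase gene Ddx6 at −1.54 (adjusted p = 0.0132, but 0.0581 without pool E and 0.0585 without K) and the cohesin loader gene Nipbl at −1.45 (adjusted p = 0.0391, up to 0.173 without K). Without a symbol, 1389986_at was at −2.30 (adjusted p = 0.00302), 1376685_at at −2.14 (0.000160), 1377774_at at −1.71 (2.16e-05) and 1390436_at at −1.70 (0.000896). The ET3x2 means of Csnk2a1 (6.67) and 1376685_at (7.40) lay under the filter levels of 6.85 and 7.52, with the same limit on the size of their differences.

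Aldoa, Sult2b1 and Ube2m were among the 21 probe sets higher in ET3x2 than in ET3x1. Aldoa, an aldolase of glycolysis, rose by 0.47 (SE 0.060, 1.39-fold, adjusted p = 0.00146), from 13.28 to 13.47 in the ET3x1 pools to 13.84 to 13.92 in the ET3x2 pools, and the sulfotransferase gene Sult2b1 by 0.60 (SE 0.094, 1.51-fold, adjusted p = 0.00792). Ube2m, of NEDD8 conjugation, rose by 0.71 (SE 0.13, 1.64-fold, adjusted p = 0.0160), a call that ended without pool G (0.0619), I (0.0588) or K (0.0764). Bcat2, which degrades branched-chain amino acids, rose by 0.53 (adjusted p = 0.0184), Slc16a6 by 0.60 (0.0277), Mettl26 by 0.49 (0.0294), Nutf2 by 0.47 (0.0356), Camsap3 by 0.44 (0.0335), Cd99 by 0.44 (0.0228) and Ap1s1 by 0.43 (0.0389). Each of these 7 ended without G, I or K, with adjusted p up to 0.173. Of list members, gamma-adducin (Add3) was at −0.83 (adjusted p = 0.0288), Sc5d at −0.39 (SE 0.065, adjusted p = 0.00675) and the plasma membrane calcium pump gene Atp2b1 at −0.54 (adjusted p = 0.0497), where the calls of Add3 and Atp2b1 ended without K (0.129 and 0.205).

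The 323 probe sets called between the congenic strains were 21 higher and 302 lower in ET3x2, for 219 genes, with 116 on RAE230A and 207 on RAE230B, and 88 had no single symbol. The median absolute log2 fold change was 0.60. The count was 146 without pool E, 488 without F (180 higher and 308 lower), 197 without G, 204 without I and 133 without K. After quantile normalisation 59 were higher and 335 lower, and with estimated array weights 714 were higher and 944 lower. Among the 302 lower, the S mean lay between the congenic means for 241, and the medians were 0.32 for ET3x1 against S and −0.29 for ET3x2 against S. Of the 302, 65 were also called in ET3x1 against S, 51 in ET3x2 against S and 1 in both. For all 21 higher the S mean lay between. Both sets were chosen for a gap between the congenic strains, so that an S mean between them was likely by that choice. The share to be expected was not worked out. Of 37 named genes called, 32 had other tested probe sets, all of which were called in 0, while 16 had one of opposite sign. Past the threshold in every alternative that tested them were 19 of 41 named probe sets. No list passed camera, with the preset or an estimated correlation (smallest adjusted p of the latter 0.879), while fry passed the cell cycle list (0.0258, 11 of 13 positive, camera adjusted p = 0.279), in which Cdk1 (0.36) and Ccnb2 (0.24) were higher when adjusted over the list alone, which ended for Cdk1 without G or I (adjusted p up to 0.0779) and for Ccnb2 without E, G, I or J (up to 0.104).

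On chromosome 3, Rtel1, a helicase that protects telomeres and whose gene lies near Edn3, was higher in both congenic strains than in S. Its probe set 1374921_at rose by 0.78 (SE 0.067, 1.72-fold, adjusted p = 3.36e-05) in ET3x1 and by 0.75 in ET3x2, where the adjusted p was 5.86e-05. The second Rtel1 probe set, 1391964_at, differed by 0.16 (SE 0.065, adjusted p = 0.403) and 0.12 (adjusted p = 0.561). Also higher in ET3x1 than in S were Csnk2a1 by 1.197 (SE 0.20, adjusted p = 0.0135), the motor protein gene Kif5c by 0.81 (0.0194), the protease gene Sppl2a by 0.78 (0.0322), the cytoskeleton gene Rnd3 by 0.78 (0.0115), the splicing gene Rbm39 by 0.65 (0.0411), the nucleolar gene Esf1 by 0.60 (SE 0.087, adjusted p = 0.00611), the ubiquitin ligase gene Traf6 by 0.53 (0.0317) and the endosome gene Gapvd1 by 0.33 (0.0413). Without pool E the adjusted p was 0.0621 for Csnk2a1, 0.0791 for Kif5c, 0.0712 for Sppl2a, 0.0550 for Rnd3, 0.143 for Rbm39, 0.114 for Traf6 and 0.133 for Gapvd1. Kif5c also missed without C (0.0531), and several other pools left out ended the calls of Sppl2a, Rbm39, Traf6 and Gapvd1. In ET3x2 against S, Zeb2 was at −0.68 (adjusted p = 0.0435), Tmem87b at −0.68 (SE 0.10, adjusted p = 0.0115), Dut at −0.50 (adjusted p = 0.0120) and Celf1 at −0.46 (adjusted p = 0.0374), and Tmem87b ended only without C among single pools (0.0512), Dut only without A (0.0528), while Celf1 and Zeb2 reached 0.197 and 0.177 without K.

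Between the congenic strains the chromosome 3 genes named were all lower in ET3x2. After Csnk2a1 came Rnd3 at −1.31 (SE 0.13, adjusted p = 0.000118), Rbm39 at −1.03 (0.000987), Rab14 at −0.94 (0.0422), Esf1 at −0.72 (0.000713), Pcmtd2 at −0.71 (0.0350), Zeb2 at −0.70 (0.0138), Tmem87b at −0.68 (0.00297), Kif5c at −0.66 (0.0288), Zc3h15 at −0.59 (0.00771), Traf6 at −0.59 (0.00771), Celf1 at −0.51 (0.00406), Phf20 at −0.51 (0.0391), Gapvd1 at −0.42 (0.00528) and Dut at −0.40 (0.0137). Without pool K the adjusted p was 0.173 for Rab14 and Phf20, 0.0805 for Pcmtd2, 0.125 for Kif5c and 0.0635 for Zeb2, and without pool E it was 0.0624 for Dut.

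Called genes were not significantly concentrated on chromosome 3, which held 7.68% of the genes tested (858 of 11170). Of the genes called it held 9 of 65 (13.8%, odds ratio 1.94, 95% confidence interval 0.841 to 3.97, Fisher's exact test p = 0.0945, adjusted p = 0.837) in ET3x1 against S, 5 of 39 (12.8%, exact p = 0.221, adjusted p = 0.799) in ET3x2 against S and 20 of 219 (9.13%, exact p = 0.440, adjusted p = 0.890) between the congenic strains. The shares moved to 8.0% without pool E in the first and to 8.16% without J, 20% without A and 30% without I or K in the second, none past the threshold. Neighbours of Edn3 were taken from a list of genes fixed beforehand, which may miss genes that lie near it. The bounds of the donor segments were not known here. Of 60 measured neighbours on that list, only Rtel1 was called in either comparison with S (exact p = 0.295 and 0.189). Between the congenic strains 0 were called (limma, exact p = 0.633). Genes outside the list, among them Pcmtd2 on chromosome 3, were not counted. The neighbours' median absolute log2 fold change was 0.0737 against 0.0812 of other genes in ET3x1 and 0.0658 against 0.0808 in ET3x2.

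**Figure D2:**
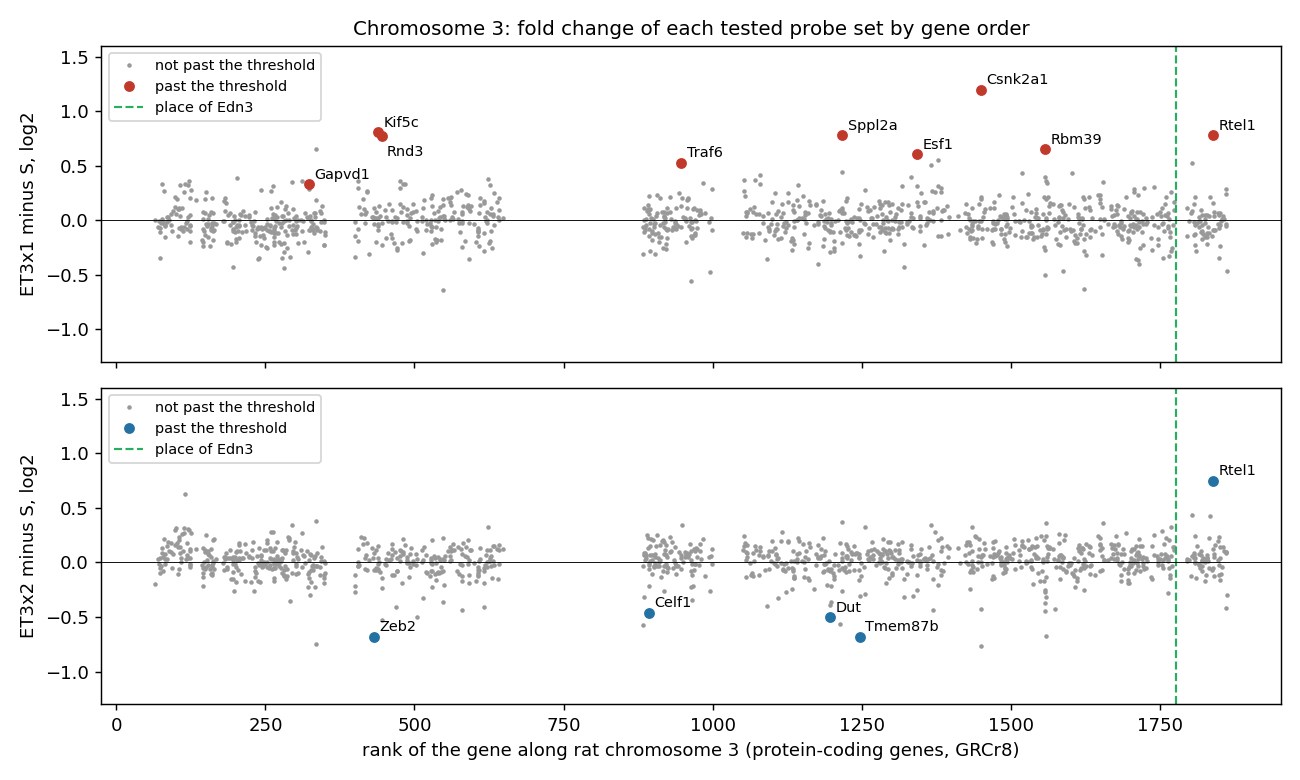
Log2 fold change against S of each tested probe set by the rank of its gene along chromosome 3, with ET3x1 and ET3x2 in separate panels, called genes coloured and a dashed line at Edn3. Edn3 is gene 1776 and Rtel1 gene 1839 of 1863, and Rtel1 is the one called gene near the line in both panels, at 0.78 and 0.75.

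Both congenic strains differed from S in the same direction in 5 probe sets, those of Rtel1 and Jchain and, without a single symbol, 1387902_a_at, 1388272_at and 1378249_x_at, which rose by 0.55 in each. A sixth, 1377774_at, went opposite ways, at 1.12 in ET3x1 and −0.59 in ET3x2. Both comparisons shared the 4 S pools. Independent lists of these sizes would share 0.0604 higher and 0.0056 lower probe sets, and simulated unchanged groups with shared S pools shared a mean of 0. Unchanged groups give almost no calls at this threshold, so that this 0 was set beforehand and is no baseline for lists of these sizes. When each congenic strain was compared with its own pair of S pools, 3 to 7 were shared over the 6 splits. The split that shared 7, with C and D for ET3x1 and A and B for ET3x2, had 10 in opposite directions, and the others had 0 or 1. Across genes, which are not independent replicates, the fold changes correlated at r = 0.415, where simulated unchanged groups gave 0.50 (0.479 to 0.530), and with separate S pools r was −0.115 to 0.252. The covariance was 0.0103 against a simulated 0.0062, a difference of 0.0041, and its mean with separate S pools was 0.00242. The shared number was 11 without pool D, 8 without G and 19 without J.

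**Figure D3:**
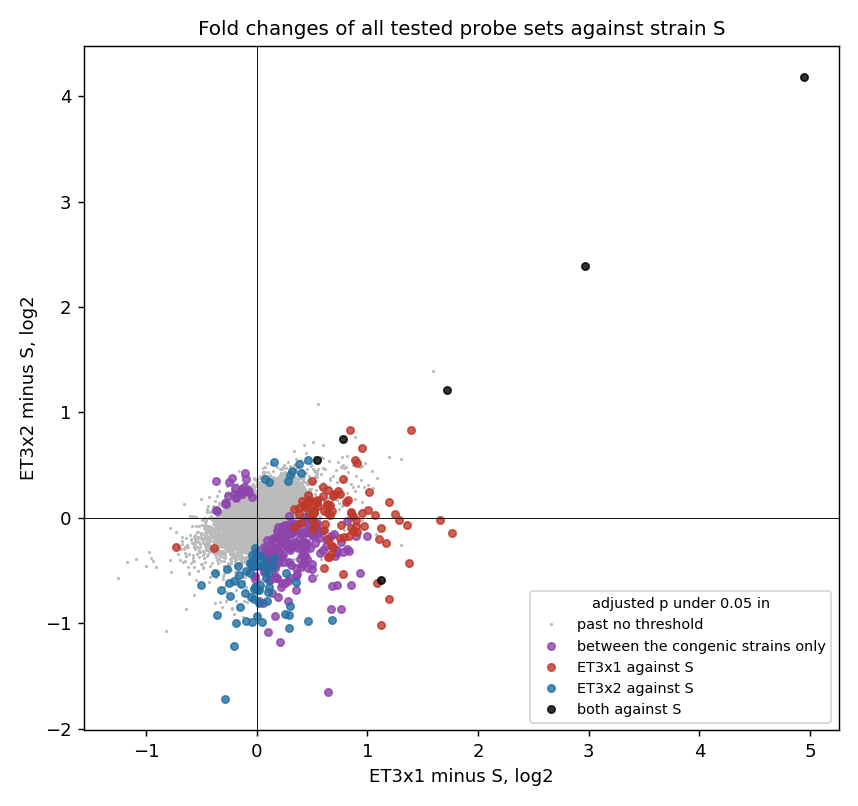
Log2 fold change of ET3x2 minus S (vertical) against ET3x1 minus S (horizontal) for the tested probe sets, each point 1 probe set, coloured by the comparison in which it passed the threshold. The probe sets called in both, given as ET3x1 and ET3x2, lie at 4.95 and 4.18 (1388272_at), 2.97 and 2.39 (1387902_a_at), 1.72 and 1.21 (Jchain), 0.78 and 0.75 (Rtel1), 0.55 and 0.55 (1378249_x_at) and, in opposite directions, 1.12 and −0.59 (1377774_at). The 302 called lower in ET3x2 than in ET3x1 lie to the lower right of the diagonal.

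The 8 genes of sodium transport, blood pressure and tubular injury that were named whether called or not, Slc12a1, Slc12a3, Scnn1a, Havcr1, Lcn2, Agt, Ace and Nr3c2, missed the threshold in all 3 comparisons. Slc12a1, the sodium-potassium-chloride cotransporter of the thick ascending limb, was at −0.39 (SE 0.11, adjusted p = 0.192) in ET3x2 against S, which passed when adjusted over the list alone (adjusted p = 0.0473 for sodium and chloride transport, 0.0189 for thick ascending limb markers, ended on leaving out any of 9 and 5 of the 12 pools, with adjusted p up to 0.174 and 0.0822), and at −0.095 (adjusted p = 0.721) in ET3x1. For the other genes the values are given in the same order, ET3x2 against S and then ET3x1 against S. Slc12a3, its thiazide-sensitive counterpart, was at 0.28 (SE 0.10, adjusted p = 0.334) in ET3x2 and 0.025 (0.935) in ET3x1, and the sodium channel subunit Scnn1a at 0.20 (0.454) and 0.092 (0.715). The injury markers were at 0.092 (0.853) and −0.081 (0.837) for Havcr1 and at 0.23 (0.452) and −0.049 (0.877) for Lcn2. Agt was at −0.066 (0.926) and −0.20 (0.680), Ace at 0.013 (0.962) and −0.061 (0.774), and the mineralocorticoid receptor gene Nr3c2 at −0.046 (0.918) and 0.21 (0.449). Between the congenic strains the adjusted p of these 8 genes ran from 0.207 (Slc12a1) to 0.783 (Agt).

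Mme and kallikrein 1 (Klk1) passed in their own lists only. Adjusted over the list alone, the peptidase gene Mme was lower in ET3x1, at −0.38 (SE 0.093, adjusted p = 0.0117), and in ET3x2, at −0.34 (adjusted p = 0.0231), which ended without A in ET3x1 (0.0529) and without A, B, I, K or L in ET3x2 (up to 0.108). Klk1, 1 of 2 genes measured of its list, was higher in ET3x2 by 0.55 (SE 0.19, adjusted p = 0.0237), which ended without A, B, I, K or L (up to 0.097). Without A, B and J together, the pools that stood apart, the difference of Klk1 was 0.32 (adjusted p = 0.0417), while Mme lost its call in ET3x1 (0.0539) and in ET3x2 (0.0562). Neither gene passed over all genes. Markers of the proximal tubule (17 measured), thick ascending limb (8), distal convoluted tubule (6), collecting duct principal cells (10), intercalated cells (8), podocytes (6) and endothelium (10) passed no camera test. The smallest adjusted p among these was 0.327 in ET3x1 against S, 0.183 in ET3x2 against S and 0.294 between the congenic strains. Over all lists, 4, 1 and 3 of 400 measured members were called in the 3 comparisons.

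**Figure D4:**
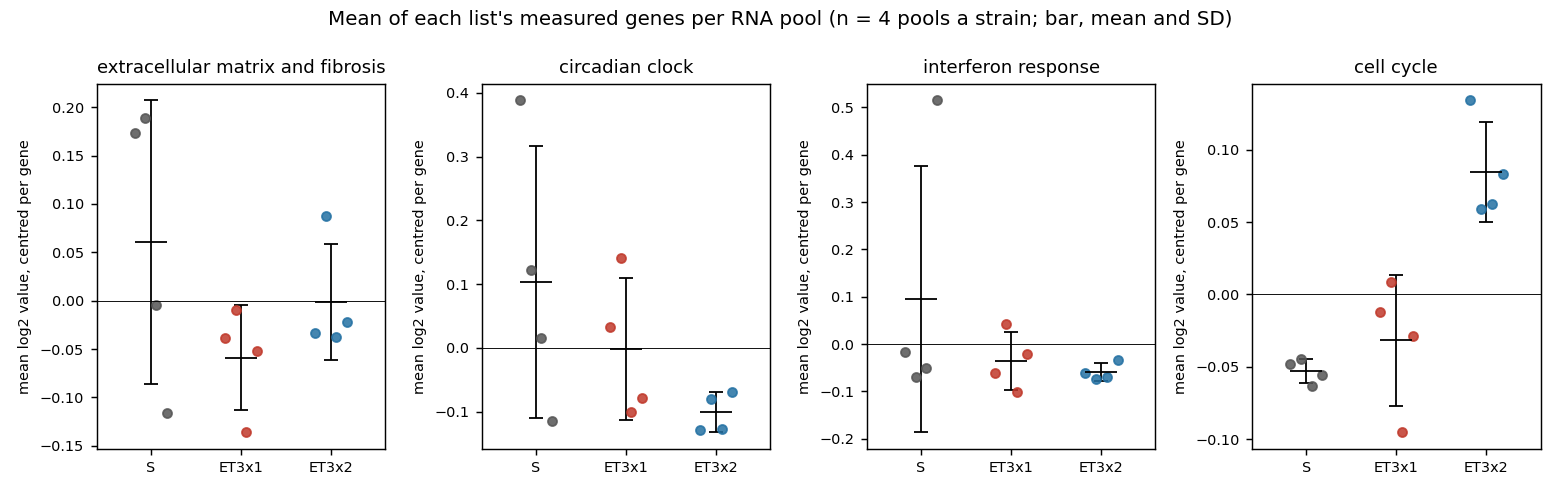
Mean log2 signal of 4 gene lists in each of the 12 pools, each gene centred on its mean over the pools, with 1 point per pool and strains coloured. The interferon list is at 0.52 in S pool D and the extracellular matrix list at 0.17 and 0.19 in S pools A and B, while the cell cycle list is at or under −0.045 in all S pools and at or above 0.059 in all ET3x2 pools.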

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

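The counts over other splits of the pools were planned, while the tests on RNA completeness, scaling, other probe sets, other antibody genes and single pools were chosen only after the results were seen.

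Slc12a1, the sodium-potassium-chloride cotransporter, stood at 10.78 in ET3x2 pool J, far from the other ET3x2 pools (nearest 10.57), and so did Smim1 at 10.18 in the same pool (nearest 10.29). The extracellular matrix list of pool J, with a mean of 0.088 (nearest −0.022), stood apart as well. Angiotensinogen (Agt) was at 9.86 in ET3x1 pool F (nearest 9.23). In ET3x1 pool G, 1388272_at was at 11.74 (nearest 12.60) and Rhoh at 7.67 (nearest 7.88). Srrm2 was at 9.75 in ET3x2 pool K (nearest 10.20). Among S pools, Camsap3 was at 9.16 in B (nearest 8.998), Rab14 at 11.08 in C (nearest 10.45) and the interferon list at 0.52 in D (nearest −0.016). These 10 were marked because 1 pool lay far from the other 3 of its strain relative to their range. The method marks about 1 in 20 groups by chance, 13.05 of the 261 tested, so that 10 is no excess, and pool J with 3 of them is one of the pools that stood apart in RNA completeness.

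Only the 83 probe sets singled out by name were searched for effects of opposite sign. For 25 of these, called against S in at least 1 strain, the effects differed between ET3x2 and ET3x1, with estimates of opposite sign. In 10 of them the smaller estimate was under 1 SE, such as 0.0035 for Tmem87b, 0.022 for Zeb2, 0.051 for Rbm5 and 0.054 for Celf1 in ET3x1, so that an effect in 1 strain alone describes these as well. Only 1377774_at was called against S in both strains, while 15 were called in ET3x1 only and 9 in ET3x2 only. The difference itself was read from the limma contrast of ET3x2 against ET3x1, with adjusted p from 2.16e-05 (1377774_at) to 0.0138 (Zeb2). Passing that contrast was a condition for being among the 25, so that these adjusted p are no independent support. For RNA-processing and translation genes the difference, ET3x2 minus ET3x1 in log2, was −1.31 for Eif5b, −1.22 for Luc7l3, −1.68 for Sltm, −1.04 for Rbm5, −1.03 for Rbm39, −0.51 for Celf1 and −0.72 for Esf1. For genes of transcription and chromatin it was −1.33 for Trps1, −0.88 for Sp1, −0.70 for Zeb2, −1.21 for Mphosph8 and −1.14 for Ubn2. For signalling, membrane and enzyme genes it was −1.96 for Csnk2a1, −1.91 for Ubxn4, −1.80 for Mgll, −1.44 for Entpd5, −1.41 for Wdfy1, −1.31 for Rnd3, −0.68 for Tmem87b, −0.59 for Traf6 and −0.42 for Gapvd1. Without a symbol, it was −2.14 for 1376685_at, −1.71 for 1377774_at, −1.70 for 1390436_at and −1.43 for 1379555_at.

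For the difference between the congenic strains the real grouping called 323 probe sets and the highest of the other splits 31, so that 1 of 35 splits called as many. That is the smallest share 35 splits can give, so chance is unlikely there but not excluded. The splits also cannot tell strain from any other difference between the 2 sets of pools. Chance was not excluded for either comparison with S. ET3x1 against S called 96, 2 of 35 splits called as many, and the highest other called 252 (pools A, B, C and F against D, E, G and H). ET3x2 against S called 75, 3 of 35 splits called as many, and the highest other called 517 (A, B, C and J against D, I, K and L). Splits that call several times the real count point to a structure of the samples other than strain, and the largest of them put pools A and B, or A, B and J, on the same side. For gene lists chance was not excluded either: 1 list was called in ET3x1 against S, where 29 of 35 splits called as many and the highest other called 7, and 4 lists in ET3x2 against S, where 4 of 35 splits called as many and the highest other called 5.

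The first pattern weighed was the lower signal of 302 probe sets, among them Srrm2, Csnk2a1 and Sltm, in ET3x2 than in ET3x1. With the actin 5' minus 3' signal as a covariate the members' median was −0.64 (−0.62 without it), and 285 of the 302 still passed. After quantile normalisation the median was −0.62 and 283 passed. The 302 were chosen as lower in these same pools, so that many were likely to pass again, and those counts are no independent support. The column medians already lay close together, which left normalisation little to change. The members' medians barely moved, which argues against RNA completeness as this control reads it, and against scaling between arrays, as the whole cause. Signal from only part of each transcript, such as unspliced RNA or alternative ends, is a candidate explanation that the values cannot decide. The other probe sets of the same genes had a median of −0.090 (272 probe sets of 162 genes), where 68.8% lay below 0 and 16 passed as lower, against −0.64 for the members of these genes. Each member was the gene's probe set with the smallest p among those called lower here, so that part of this gap was built in by the choice. The other probe sets were thus also lower on balance, since random sets of probe sets gave medians of 0.022 to 0.057, but by much less than the members, so that a smaller fall of whole transcripts may be part of the pattern. Strain itself, an unrecorded difference in the handling of the strains' RNA, and other aspects of RNA quality that the actin control does not read stay open and were not tested.

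The second pattern was the higher signal of Jchain and 1388272_at in both congenic strains. The probe set 1388272_at has no symbol and was taken in for its rise, the largest in ET3x1 against S. No value here ties it to antibodies. In these 2 probe sets the difference did not rest on a few pools, since the lowest congenic pool exceeded the highest S pool by 3.33 for 1388272_at (pooled SD 0.419) and by 0.838 for Jchain. Both were picked for their rise in the same data, so that such a separation was likely beforehand and is no independent support. More antibody-secreting cells could not be decided: the mean of the 7 other genes measured of a list of 18 differed by 0.0204 between congenic and S pools (exact permutation test, two-sided, p = 0.729 over 495 splits), with an upper 95% limit of 0.162, and that list was drawn up after Jchain was seen. All 8 congenic pools lay above all 4 S pools in 5 of the 15 probe sets of that list, the 2 of Jchain and those of Ighl2, Iglc1 and, by only 0.0080, Mzb1, and not in the other 10, among them those of Pou2af1, Creld2, Edem1, Ell2, Tnfrsf17 and Sdf2l1. A transcript variant specific to the strain, antibody gene alleles that differ between the strains, and a difference in immune cells may each remain open, and what 1388272_at detects was not analysed here.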

How the results depend on the processing

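The alternatives with the actin covariate and without pools A, B and J together were tests chosen only after the results were seen. No called named probe set changed direction under any alternative that tested it, while genes named without a call, such as Slc12a3 and Agt, changed sign in some. Of the called, 11 of 27 (ET3x1 against S), 5 of 28 (ET3x2 against S) and 19 of 41 (ET3x2 against ET3x1) stayed past the threshold in all alternatives that tested them. A probe set left out by the filter at the 50th percentile was not counted for that alternative. For the called named probe sets, alternatives other than omissions of 1 pool kept the call in 1108 cases and ended it in 123, and omissions of 1 pool kept it in 862 and ended it in 290. For genes named without a call, alternatives gave a call in 5 cases and omissions in 1. The number of probe sets called depended on the fit more than on scaling or filter. A fit of only the strains compared called 51 in ET3x1 against S, 42 in ET3x2 against S and 386 between the congenic strains, and weights by rats called 79, 45 and 473 (66 higher, 407 lower). Estimated array weights called 164, 419 (136 higher, 283 lower) and 1658 (714 higher, 944 lower) in the 3 comparisons, where the unweighted fit called 14 higher and 61 lower in ET3x2 against S and 21 higher and 302 lower between the congenic strains. The actin covariate called 215, 432 (141 higher, 291 lower) and 502 and retained 96, 75 and 303 of the original calls. Without A, B and J, ET3x2 against S called 17. The cause of these moves was not tested. A minimum of 1.5-fold, which can only remove calls, left 39 and 175 in the comparisons of ET3x2 with S and with ET3x1. Leaving out 1 pool gave 41 to 118, 19 to 167 and 133 to 488.

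The number of probe sets shared by both comparisons with S, 5 in all pools, was 8 with an untrended prior, 8 with adjustment over both arrays, 17 with array weights, 29 with the actin covariate, 3 or 7 with separate S pools, and 5 to 19 on leaving out 1 pool. The share of called genes on chromosome 3 passed in no alternative. Gene lists past the threshold numbered 2 in ET3x1 against S without a filter, 1 in ET3x2 against S and 1 between the congenic strains with the filter at the 50th percentile, 1 in ET3x2 against S without A, B and J, 0 in both comparisons with S at an estimated correlation, and 0, 2 and 1 by fry. On leaving out 1 pool they numbered 0 to 2, 3 to 5 and 0. The cause was not tested. No arrays' background signal was given, so that its limit on dim probe sets is unknown. Other offsets apply to linear tables only, and camera has no robust prior, so neither was run.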

Other observations

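The tests in this part, on gene families, single genes of the interferon list, the second Rtel1 probe set and the neighbours of Edn3, were chosen only after the results were seen. Genes that act on RNA and chromatin were over-represented among those lower in ET3x2 than in ET3x1. With families defined by symbol prefix, 14 of 138 genes of RNA binding and splicing were called lower (10.1% against 1.68% of other genes, odds ratio 6.61, Fisher's exact test, adjusted p = 5.29e-07), 12 of 99 chromatin genes (12.1% against 1.69%, odds ratio 8.02, adjusted p = 5.29e-07) and 9 of 187 zinc finger genes (4.81% against 1.73%, adjusted p = 0.0126). Of the housekeeping families, 0 of 47 ribosomal protein genes, 0 of 75 respiratory chain genes and 0 of 46 proteasome genes were called lower in limma, which does not differ from the share of other genes (exact adjusted p = 1, 0.969 and 1). With 1.79% of other genes called lower, families of these sizes are too small for a count of 0 to differ. The counts therefore show no contrast with the other families. Tested on all their members by camera at the preset correlation, chromatin genes (median −0.041, adjusted p = 0.000193), RNA-binding genes (median −0.029, adjusted p = 0.000548) and ribosomal protein genes (median −0.056, adjusted p = 0.00165) were lower on balance, and no family passed with an estimated correlation (smallest adjusted p = 0.535). Genes with more probe sets have more chances to be called, and this was not tested.

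S pool D carried high signal of interferon-induced genes. Isg15, an antiviral ubiquitin-like protein, was at 10.90 in pool D against 9.03 to 9.37 in the other S pools, and 9.12 to 9.69 in the congenic pools. Irf7, the interferon-inducible transcription factor, was at 11.24 against 9.67 to 10.33 in the other 11 pools, Usp18 at 9.44 against 8.60 to 8.87, Ifi44 at 8.29 against 7.36 to 7.66 and Oas1a at 9.11 against 8.43 to 8.74. Pool D held RNA of 2 rats, and no explanation was tested.

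Among other antibody-related probe sets, Ighl2 differed by 1.59 (SE 0.31, adjusted p = 0.0598) in ET3x1 and by 1.39 (adjusted p = 0.109) in ET3x2 against S, Iglc1 by 0.79 (adjusted p = 0.190) and 0.47 (0.450), and Mzb1, of the endoplasmic reticulum of plasma cells, by 0.21 (SE 0.055, adjusted p = 0.126) and 0.12 (0.484). None passed, although the lowest congenic pool exceeded the highest S pool by 0.45 for Ighl2, 0.058 for Iglc1 and 0.0080 for Mzb1.

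Rtel1 was the 1 called gene among the measured neighbours of Edn3 on the list fixed beforehand. These neighbours did not differ more in size than other genes. Their median absolute log2 fold change in ET3x1 against S was 0.0737, at percentile 25.7 of random gene sets, and that of other genes 0.0812. A size without sign cannot show a shift in 1 direction. Of 61 measured list members, wherever placed, 27 were positive and 34 negative in ET3x1 against S. In ET3x2, 47 were positive and 14 negative against S (median 0.042, against 0.025 over all probe sets). The counts were the same against ET3x1 (median 0.054, against 0.032). A common shift was not tested. The second Rtel1 probe set differed by 0.159 in ET3x1 (95% interval 0.012 to 0.307) and by 0.121 in ET3x2 (−0.026 to 0.269), well under the 0.78 and 0.75 of the first. A change in only part of the transcript, or a strain variant under the first probe set, may therefore account for the signal, and a regulatory allele acting on some Rtel1 transcripts stays open, untested.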
